A study of Mus musculus with 160 samples.

How the data were processed

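RNA was sequenced from striatum, cortex, tibialis muscle, heart and liver of 32 mice, so that 160 libraries fell into 20 groups, each of 1 tissue and 1 treatment arm. Each group held 8 libraries, 4 from males and 4 from females. Group, sex and replicate number came from the sample titles, and each library's column in the deposited tables was found through the identifier that its label gives. That identifier also carries an animal number, which showed that each of the 32 animals gave all 5 tissues and that the same animal has different replicate numbers in different tissues. Tissue was collected at 6 months of age, and total RNA was extracted with the Qiagen miRNeasy kit and made into libraries with standard Illumina protocols, per the labels.

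CASAVA 1.8.2 is the only software named in the submitters' processing notes. The aligner, the genome build, the annotation and the program that counted reads are not given in the sources used here, nor is it stated whether counting used the strand. The deposited count table holds estimated counts, with 1 value per gene and library for 43432 genes named by Ensembl identifier. Of its values above 0, 26.3% were not whole at a tolerance of 0.001, so the values were rounded to whole numbers before testing. The deposited FPKM table holds FPKM, fragments scaled by transcript length and library total, for the same genes and libraries. Within a gene, the ratio of FPKM to count followed the library total with a largest relative deviation of 1.78e-06, so that no scaling between libraries beyond the total was found in it. Gene symbols were taken from the reference table of gene names. It matched 42462 identifiers, and the 970 without a match held 0.138% of all counts. No count was found in any library for 9916 genes.

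Library totals ranged from 29.8 M to 44.9 M estimated counts (M for mega). Counts without molecular identifiers are not independent molecules, so the depth sets only the counting error. Sequencing batches are not given in the labels. The column names of 60 libraries end in a lane and an index and those of 100 in a number, and this difference was used as an added covariate in an alternative chosen after the data were seen. No pair of libraries had identical columns.

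Each tissue was analysed on its own in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, library sizes were scaled by TMM, and dispersions and quasi-likelihood fits were robust. The model held group and sex over all 32 libraries of the tissue, so that the groups shared 1 estimate of the spread. The contrasts were Q175 vehicle against WT vehicle, each dose against Q175 vehicle, the doses against each other and each dose against WT vehicle. Quasi-likelihood F tests were adjusted by the Benjamini-Hochberg method over the genes tested in that tissue, with a threshold of 0.05. Standard errors of log2 fold changes were obtained from the F statistics. Interactions with sex were tested in the same way. Differences of an effect between striatum and another tissue were tested with limma 3.58.1 on each animal's difference in log2 CPM (prior count 2) between striatum and the other tissue, over genes kept in both, with sex as a covariate. DESeq2 1.42.0 gave an alternative count for each contrast.

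Gene lists for cell types, pathways and complexes, 47 in all, were written before the data were examined, as were the design, the first set of alternatives and the rule for the genes named. Lists with at least 3 members among the genes tested entered camera in limma with a preset correlation of 0.01 between genes, adjusted over the lists tested in that tissue and contrast. Camera with an estimated correlation and fry gave the alternatives. For each list the number of members past the threshold was counted over all genes tested and again adjusted over the list alone.

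The genes named were Htt and the class IIa histone deacetylases in every comparison. To these were added, for the genotype contrast in striatum, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM in either group and a symbol that is not a predicted or clone name. The same rule took 5 and 5 genes in every other tissue for the genotype and dose contrasts. For each list with members past the threshold, up to 2 members that rose most and 2 that fell most were added. Where no gene passed, the 3 with the smallest p were taken. Y-linked genes and the RNAs of X inactivation were left out. Genes given as further examples were chosen after their values were seen.

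Reversal of the genotype effect by a dose was measured as the correlation across genes between the genotype effect and the dose effect. Both share the Q175 vehicle libraries, so these were split into equal parts within sex, in 18 ways. Each part served a single contrast at a time, and both assignments of the parts entered the mean and the range. The unsplit value was set beside 10 simulations of unchanged groups. The simulations drew each gene independently. Genes are not independent replicates, so no p is given for these correlations.

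The share of transcripts from another tissue was estimated for each library from up to 50 genes per source tissue, each with a median of at least 50 CPM in the source and over 1000 times the median of the receiving tissue. This estimate was chosen after the data were seen. Libraries above 0.05%, 17 in all, were left out in an alternative, as were, in another, the 6 libraries holding over 10 CPM of Xist in a male or over 1 CPM of Ddx3y in a female. Both were chosen after the data were seen. Further alternatives were DESeq2, DESeq2 size factors in the edgeR fit, no filter, only the groups compared, no sex term, the replicate number as a block, 2 surrogate variables from sva 3.50.0, without outlying libraries (median correlation with the rest of the group over 4 scaled deviations below the tissue's median), limma on log2 of FPKM plus 1, a threshold of 0.1, and leaving out each library in turn.

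The tests were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. For Q175 vehicle against WT vehicle, the share of 1.5-fold changes recovered was 54.1% among 17075 genes in striatum, 52.0% among 17431 in cortex, 24.2% among 14590 in tibialis, 64% among 15877 in heart and 57% among 14850 in liver. For 2-fold changes the shares were 87%, 69%, 64.6%, 86.9% and 74%. Gene positions were taken from GENCODE M21 on GRCm38 and serve only to place genes relative to Htt, because the authors' build is not given in the sources used here.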

Results

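RNA was measured in striatum, cortex, tibialis muscle, heart and liver of 32 mice at 6 months of age. Q175 mice carry 1 copy of Htt with an expanded CAG repeat, the mutation of Huntington's disease, and wild-type (WT) mice do not. CHDI-00390576 inhibits class IIa histone deacetylases (Hdac4, Hdac5, Hdac7 and Hdac9) and was given by mouth b.i.d. from 4 weeks of age. In each tissue, WT mice on vehicle, Q175 mice on vehicle, and Q175 mice on 30 or 100 mg/kg made up 4 groups of 8 libraries, 4 from males and 4 from females. Library totals ranged from 30.7 M to 38.5 M estimated counts in striatum, 29.8 M to 39.3 M in cortex, 36.1 M to 44.9 M in tibialis, 33.5 M to 41.7 M in heart and 33.5 M to 41.4 M in liver. Values below are counts per mega of the library (CPM, scaled by TMM) as mean ± SD over 8 libraries, and log2 fold changes ± standard error with edgeR's adjusted p.

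**Figure D1:**
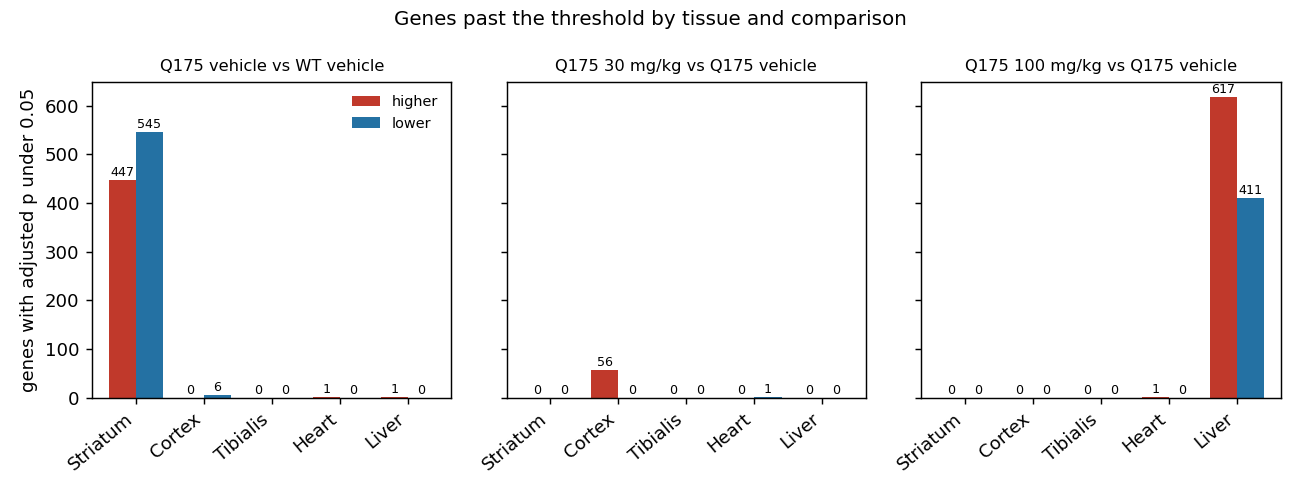
Number of genes past an adjusted p of 0.05 (vertical axis) in each tissue and comparison, with bars for higher and lower genes. Genotype gave 992 genes in striatum, and 100 mg/kg gave 1028 in liver and 0 in striatum.

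The targeted gene came first, as a check of the labels. Striatal Htt fell from 129.6 ± 14.2 CPM in WT to 98.4 ± 11.8 in Q175 on vehicle (log2 −0.40 ± 0.08, adjusted p = 0.00231), and was 95.3 ± 9.94 at 30 mg/kg and 91.3 ± 10.7 at 100 mg/kg. That call was lost with limma on FPKM. Htt differed by −0.41 ± 0.16 in cortex (adjusted p = 1), −0.61 ± 0.19 in tibialis (0.177), −0.39 ± 0.18 in heart (0.411) and −0.39 ± 0.15 in liver (0.723), none past the threshold. The class IIa deacetylases, which hold back MEF2 transcription factors, did not pass it for genotype or dose in any tissue with edgeR. In striatum, Hdac5 was 25.8 CPM in WT, 31.5 in Q175 on vehicle, 23.0 at 30 mg/kg and 22.6 at 100 mg/kg. Hdac4 was 21.5, 20.8, 19.3 and 20.2 CPM in the same order, Hdac7 was 7.52, 9.12, 7.28 and 6.58, and Hdac9 was 16.4, 14.9, 16.1 and 16.5.

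The comparison of Q175 with WT on vehicle asks what the expanded allele changes. In striatum, transcripts that mark medium spiny neurons, the main neurons there, fell. Cnr1, the cannabinoid receptor CB1, fell 2.11-fold from 633.5 ± 98.9 to 298 ± 52.9 CPM, and Scn4b, a sodium channel subunit, fell 1.91-fold. Drd1, the dopamine receptor of the direct pathway, and Penk, the enkephalin precursor of the indirect pathway, fell as well. Wt1 and Sfmbt2 were among the genes that rose. Of 17229 genes tested, 447 rose and 545 fell (DESeq2, 619 and 804), 335 of them by over 1.5-fold and 108 by over 2-fold. With limma on FPKM more rose than fell, and fewer passed without libraries over the limit for another tissue.

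**Figure D2:**
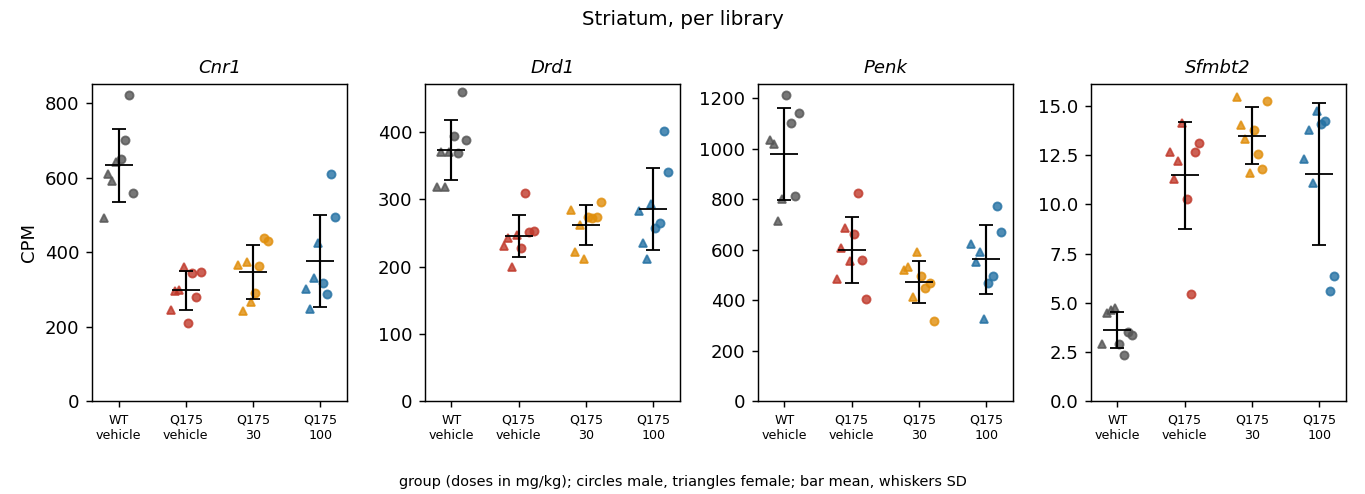
CPM of Cnr1, Drd1, Penk and Sfmbt2 (vertical axes) in each striatal library by group, with circles for males, triangles for females and bars for mean ± SD. Cnr1 averaged 633.5 CPM in WT and 298 in Q175 on vehicle, and Sfmbt2 3.62 and 11.5.

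Among neuronal genes, Pde10a, the phosphodiesterase of medium spiny neurons, fell from 2053 to 1101 CPM (log2 −0.90 ± 0.12, adjusted p = 2.47e-05). Rgs4, a brake on G protein signals, changed by −0.81 ± 0.11 (2.08e-05), Ryr1, a calcium release channel, by −1.24 ± 0.19 (0.000107), and Drd1 by −0.61 ± 0.09 (4.92e-05), from 374 ± 44.7 to 245 ± 31.0 CPM. Penk went from 980.1 ± 182 to 598 ± 130 CPM. Of 33 medium spiny neuron genes, 19 fell and 0 rose, and adjusted over the list alone 21 fell and 1 rose, Tac1 (substance P), at 0.21. The median was −0.41 (camera adjusted p = 1.25e-21, and adjusted p = 0.0308 with an estimated correlation, the only striatal list that held there of the 12 called among 30). Of 8 indirect pathway genes, 3 fell in both counts (Penk, Upb1 and Gpr6; median −0.31, adjusted p = 0.00056, and adjusted p = 0.0965 with an estimated correlation). Of 10 direct pathway genes, 2 fell, and adjusted over the list alone 2 rose and 2 fell (0.325). Of transcription factors that follow neuronal activity, Egr2 changed by −1.23 ± 0.29 (adjusted p = 0.00923), Egr1 by −0.40 and Ier5 by −0.47, and of 19 immediate early genes 3 fell, with 5 adjusted over the list alone (0.0013, and adjusted p = 0.425 with an estimated correlation). Of 35 neuronal ion channels, 7 fell, among them Cacna1e (−0.42) and Cacna2d3 (−0.39), and 1 rose, Scn3b (0.26), with 8 and 1 adjusted over the list alone (5.29e-05, and adjusted p = 0.26 with an estimated correlation).

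Some homeobox and Polycomb target genes, which Polycomb complexes keep silent in neurons, rose. Wt1, a zinc finger factor of kidney and gonad, rose from 0.109 ± 0.0884 to 3.8 ± 1.76 CPM (log2 5.04 ± 0.65, adjusted p = 1.26e-05). Onecut1 rose by 3.81 ± 0.76, from 0.0684 to 0.938 CPM, and Hoxa7 by 1.91 ± 0.39, from 0.0664 to 0.262 CPM. Both lay under 1 CPM and were chosen after their values were seen. Hoxc4 had 0 counts in WT striata and a count in 7 of 8 Q175 striata on vehicle, at least 4.07-fold higher against a floor of 3 counts per library. Of 15 such genes 4 rose and 1 fell (Tfap2b, −0.93), with the same numbers adjusted over the list alone (0.0239, and adjusted p = 0.415 with an estimated correlation). Sfmbt2, a Polycomb protein, rose by 1.67 ± 0.18 (5.92e-07), from 3.62 ± 0.898 to 11.5 ± 2.70 CPM, and Cbx8, another, by 1.05 ± 0.17 (0.000145). In 3 Q175 striata, vehicle M2 (0.0603 CPM) and 100 mg/kg M3 (0.135) and M4 (0.0887), Wt1 was within the WT range, which reached 0.267 CPM. Of 44 clustered protocadherins, which are adhesion genes with shared exons and so uncertain one by one, 9 rose, Pcdhb3 by 0.69 and Pcdhb9 by 0.59, and adjusted over the list alone 14 rose and 2 fell (0.0119, and adjusted p = 0.683 with an estimated correlation). Of 14 deacetylases and sirtuins, 2 rose in both counts, Hdac1 by 0.41 ± 0.07 (0.000508) and Sirt5 by 0.32 (list 0.00533, and adjusted p = 0.425 with an estimated correlation).

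**Figure D3:**
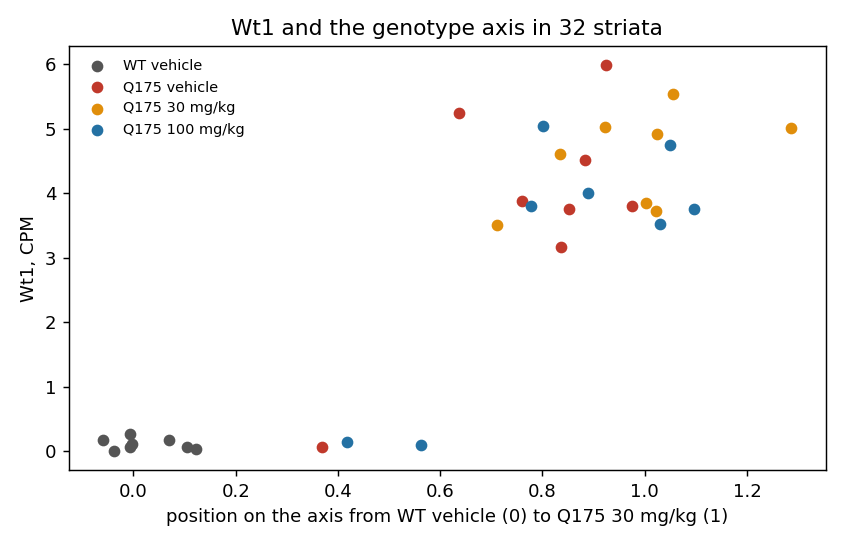
Wt1 in CPM (vertical axis) against the position of each striatal library between the WT mean (0) and the Q175 30 mg/kg mean (1) over the genes that differ there (horizontal axis), with a point per library coloured by group. The 3 Q175 striata with Wt1 at the WT level lie between 0.368 and 0.562, above the highest WT at 0.123.

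Other large rises were in Shox2, a homeobox gene (2.13 ± 0.38), Crnde, a long non-coding RNA (2.12 ± 0.35), Gemin4, of the SMN complex (2.10 ± 0.62), Dsp, a desmosome protein (1.83 ± 0.28), and Abhd1, a hydrolase gene on the chromosome of Htt (1.68 ± 0.25). Adamts19, a metalloprotease (1.41 ± 0.25), Ifnlr1, the interferon lambda receptor (1.32 ± 0.26), and Vill, of the villin family (1.22 ± 0.22), followed. Oligodendrocyte genes of myelin fell in 5 of 14 cases in both counts, among them Mal by −0.52 and Ugt8a by −0.56 (0.0157, and adjusted p = 0.425 with an estimated correlation). Slc1a2, the astrocyte glutamate transporter, changed by −0.44 ± 0.11, the only 1 of 11 astrocyte genes (0.129), and adjusted over the list alone 1 rose and 1 fell. Npas2, a clock factor, changed by −0.48 ± 0.09, 1 of 21 circadian genes (0.0157, and adjusted p = 0.26 with an estimated correlation). Herpud1, of the unfolded protein response, rose by 0.25 (1 of 25 genes, 2 adjusted over the list alone, 0.0694), Plk2, a p53 target, changed by −0.31 (1 of 17), and Insig1, of cholesterol control, by −0.36 (1 of 25, 0.448). Genes of nuclear oxidative phosphorylation (74, adjusted p = 5.29e-05) and ribosomal proteins (72, 0.000618) lay higher and those of the mitochondrial genome lower (13, 0.0367), with 0 members called by edgeR and adjusted p = 0.617, 0.683 and 0.683 with an estimated correlation.

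Liver transcripts made up most of the largest falls. Alb (serum albumin) changed by −4.97, Gc by −3.66, Hpx by −3.09, Rgn by −3.01, Apoa2 by −2.84, C3 by −2.57, Uox by −2.52 and Car3 by −2.22, and WT replicate M1 held 0.242% of liver transcripts. Of 136 tested genes that are over 100 times higher in liver, 26 fell and 0 rose, so that 519 of the falls were in other genes. Wnt8b (−2.39 ± 0.32, adjusted p = 2.37e-05), a Wnt ligand, and Zbed6 (−5.22, 0.048), a transposon-derived repressor, were the other large falls by the rule. Chosen after their values were seen, Gpx6 (−1.94), Phex (−1.68) and Sec14l3 (−1.54) fell among genes not over 100 times higher in liver. Krt9 (−1.0 ± 0.09, 1.92e-08), chosen in the same way, fell as well. The liver genes named, Zbed6, Gemin4, Sirt5, Scn3b, Herpud1, Plk2, Insig1, Cacna1e, Ier5, Tfap2b and Htt each lost their call in at least 1 alternative. The count was 418 without libraries over the limit for another tissue and 3596 with 2 surrogate variables.

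The doses in Q175 ask whether the inhibitor changes expression in the diseased tissue. In striatum 0 genes passed with edgeR at 30 mg/kg (2873 at an unadjusted p under 0.05, DESeq2 0), 0 at 100 mg/kg (4243, DESeq2 3) and 0 between the doses (247, DESeq2 0). Lowest in p at 30 mg/kg were Gm26756 (0.65), Tipin, of the replication fork (0.42), and Prr5l, an mTOR partner (0.30), each at adjusted p = 0.288. The higher dose had Gm16124 (0.90), Gm16793 (0.75) and Banp, a matrix-binding protein (−0.60), each at 0.199, lowest. Of 30 lists, 6 were called at 30 mg/kg: ribosomal proteins lower (1.65e-05), the mitochondrial genome higher (6.63e-05), protocadherins higher (0.000707), and the unfolded protein response (0.00135, 3 members lower adjusted over the list alone), oxidative phosphorylation (0.00228) and medium spiny neuron genes lower (median −0.15, 0.0228). None was called with an estimated correlation (camera adjusted p = 0.827 for each). The 100 mg/kg group had ribosomal proteins (4.98e-05), the unfolded protein response (0.000296, 8 members adjusted over the list alone), oxidative phosphorylation (0.00303), deacetylases and sirtuins (0.0123) and microglia genes (0.0313, 4 members) lower, and the mitochondrial genome (0.00039) and protocadherins (0.0376) higher. With an estimated correlation their adjusted p was 0.864.

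Reversal asks whether a dose moves striatal genes back toward WT. With the vehicle libraries split so that no library served both contrasts, the correlation across genes of genotype and dose effects was −0.149 at 30 mg/kg (range −0.303 to 0.131 over 18 splits) and −0.210 at 100 mg/kg (−0.362 to 0.0947). Over the genes called for genotype it was −0.214 and −0.346, and with genes chosen on the genotype part alone 0.133 and −0.146. The unsplit values were −0.494 and −0.552 (covariance −0.0465 and −0.0536), beside −0.268 and −0.278 (covariance −0.0226 and −0.0235) in simulations without a dose effect, where sharing the vehicle libraries alone gives a negative value. With the vehicle libraries split between the doses, their effects correlated at 0.369 (range 0.105 to 0.515), beside −0.000341 in split simulations without a dose effect. In cortex the same measure was −0.321, beside 0.0136. Cortex 30 mg/kg F4 and M3 held 27.2% and 6.34% of tibialis transcripts, which enter the 30 mg/kg effect. The cortex value therefore cannot be read as opposite effects of the doses. The simulations drew each gene independently, so they lack variation that genes share within a library. They cannot tell a dose effect from such variation, in the split or the unsplit values. On the axis from the WT mean (0) to the 30 mg/kg mean (1), vehicle M2 stood at 0.368 and 100 mg/kg M3 and M4 at 0.417 and 0.562. The other Q175 striata, on vehicle or either dose, stood at 0.637 to 1.29. How far these 3 striata set the striatal correlations was not tested. Against WT, 572 genes were higher and 580 lower at 30 mg/kg, and 414 and 437 at 100 mg/kg. Split values elsewhere were, at 100 mg/kg, 0.207 in cortex and −0.535 in tibialis (−0.0876 on FPKM), and at 30 mg/kg 0.230 in liver and −0.0876 in heart. Tibialis WT F3, WT M4 and 100 mg/kg M1 held cortex transcripts, which lower the genotype effect and raise the dose effect for brain genes. The tibialis value therefore cannot be read as reversal. Genes are not independent replicates.

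In cortex, few genes passed for genotype, and medium spiny neuron genes lay lower as a list. The 6 genes that fell were Cd4, the T cell co-receptor (−1.13 ± 0.20, adjusted p = 0.0317), Slc4a11, a borate family transporter (−1.43 ± 0.27), Stard8 (−0.41), Mas1, an angiotensin peptide receptor (−0.39), Hipk4, a kinase (−0.38), and Gm15721 (−0.75 ± 0.13, 0.0317). Each call was lost in an alternative (DESeq2 gave 34). Without Q175 vehicle M1, M2, M4, F1 or F3 or WT M3, F3 or F4 the count was 0. It was 1 without WT M2 or vehicle F2, 2 without 30 mg/kg M1, M3 or F2 or 100 mg/kg F2, 3 without 100 mg/kg M4, 11 without WT F2, vehicle M3 or 30 mg/kg F4, and 13 without WT F1. Of 33 medium spiny neuron genes, 9 fell adjusted over the list alone and 0 over all genes (median −0.27, camera adjusted p = 4.7e-24, and 6.91e-05 with an estimated correlation), among them Pde10a (−0.68), Drd1 (−0.41) and Drd2 (−0.75). Of 8 indirect pathway genes 3 did (−0.58, 3.69e-07, and 0.0129 estimated). The share of striatal transcripts in cortex libraries was not estimated. A genotype effect within cortex on these lists therefore cannot be told from differing amounts of striatal tissue in the libraries. Choroid plexus genes, such as Folr1 (−1.78), were lower in 7 of 11 cases adjusted over the list alone (3.16e-07, and adjusted p = 0.208 with an estimated correlation). Immediate early genes (1.21e-07, and adjusted p = 0.159 with an estimated correlation) and direct pathway genes (0.0121, 0.159) were lower, and interferon-induced genes higher (1.93e-05, 0.0856). Ion channels (0.00635, 0.601), excitatory neuron (0.0308, 0.122), astrocyte (0.0152, 0.0633) and blood genes (0.0424, 0.601) made up the rest of 10 called lists of 30.

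At 30 mg/kg, the genes that passed in cortex were those of skeletal muscle, and they came from few libraries. Myh4, the fast myosin, averaged 1085 ± 2553 CPM against 2.26 on vehicle (8.41 ± 1.91, adjusted p = 0.0436). Tnnc2 (8.31), Tnni2 (8.07), Mylpf (7.92), Mb, myoglobin (7.98), Hrc (6.21) and Klhl41 (5.49), all of the muscle fibre, Aqp1, a water channel (4.02), and Tbx15, a limb factor (2.99), went with it. Of 56 genes that rose (DESeq2 3 in all), 53 had a tibialis median over 100 times that of cortex, and 30 mg/kg F4 and M3 held 27.2% and 6.34% of tibialis transcripts. The count was 0 without either, or without vehicle M1, M2, M4, F1, F2, F3 or F4. It was 34, 35, 36, 36, 35 and 35 without 100 mg/kg M1, M2, M3, F1, F3 and F4, and 104, 108, 99, 95 and 88 without 30 mg/kg M1, M2, F1, F2 and F3. Myh4, Tnni2, Mb and Mylpf changed sign without libraries over the limit for another tissue. Of 18 MEF2 targets, the genes class IIa deacetylases hold back, 7 rose and adjusted over the list alone 10 (median 0.82, 0.0329, and adjusted p = 0.725 with an estimated correlation), with an adjusted p of 0.573 without libraries holding transcripts of the other sex. The 5 other called lists had adjusted p between 0.725 and 0.803 with an estimated correlation. At 100 mg/kg 0 genes passed (610 at an unadjusted p under 0.05, DESeq2 1), the lowest in p being Gm15975 (0.88), ENSMUSG00000097102 (−0.54) and Gm12481 (−7.0), at adjusted p = 0.811. Ribosomal proteins (1.48e-09), oxidative phosphorylation (1.75e-09) and the unfolded protein response (1.72e-05) lay lower and protocadherins (7.36e-07) and ion channels (0.00892) higher, at adjusted p = 0.593 with an estimated correlation.

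In tibialis 0 genes passed in any comparison with edgeR, and counts at an unadjusted p under 0.05 and by DESeq2 were 1176 and 4 for genotype, 165 and 10 for 30 mg/kg, 758 and 1 for 100 mg/kg, 418 and 10 between doses, and 1267 and 11, and 647 and 2, for the doses against WT. Without 100 mg/kg M1, which held 11.7% of cortex transcripts, genotype gave 349 genes (8 higher, 341 lower). The doses against WT gave 283 (3 higher, 280 lower) and 341 (20 higher, 321 lower). WT F3 and M4, which also held cortex transcripts, stayed in these fits. Genes lower than in WT there cannot be told from brain RNA in WT. Nerve and Schwann cell genes were lower in Q175, 4 of 9 adjusted over the list alone (median −0.74, 1.82e-05, and adjusted p = 0.319 with an estimated correlation), among them Mbp (−2.62). WT F3 and M4 held 11.8% and 6.26% of cortex transcripts, which hold Mbp too, and without libraries holding transcripts of the other sex the list was at 1.17e-06. Of genes compared at 100 mg/kg, 26 PPAR targets of fatty acid use were lower (median −0.20, 2e-09, and adjusted p = 0.0501 with an estimated correlation), as were MEF2 targets (0.000339, 0.126, 1 member adjusted over the list alone), and slow (0.000339, 0.208) and fast fibre genes (0.000304, 0.255), while nerve genes were higher (0.00202, 0.208), the last value of each being that with an estimated correlation, at which none of the 10 lists was called. Cortex RNA in 100 mg/kg M1 bears on these lists, and without libraries holding transcripts of the other sex the PPAR list was at 4.23e-05, MEF2 at 0.0054, slow fibre at 0.00387, fast fibre at 0.0142 and nerve at 0.0184. Trim63, the atrophy ligase MuRF1, was 141 CPM at 100 mg/kg and 249 on vehicle (−0.79), Pcdh18 differed by 0.68 and Tmem140 by −0.79 (0.952 each). Lowest in p for genotype were Sh2d4a (0.93), Ctsl, a lysosomal protease (0.37), and Slc4a10 (−5.08), each at 0.162, the last a brain transcript at 6.31 ± 11.3 CPM in WT, where F3 and M4 held cortex RNA. The 30 mg/kg group had Lrrc15 (−4.31) and the hair keratins Krt71 (−7.32) and Krt27 (−7.43), each at 1.0, lowest in p, with interferon-induced genes higher (0.000136, and adjusted p = 0.218 with an estimated correlation).

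In heart single genes passed. Abhd1 rose in Q175 from 1.97 ± 0.799 to 8.54 ± 2.3 CPM (2.18 ± 0.32, adjusted p = 0.00211, DESeq2 95 genes). The count of 1 was 2 without vehicle F1, 30 mg/kg M1, 100 mg/kg M1 or F4 or WT M2, 3 without vehicle F4 or 100 mg/kg M4, and 4 without vehicle M2. At 30 mg/kg 2900052N01Rik fell (−1.34 ± 0.21, 0.00589, from 0.859 to 0.336 CPM, DESeq2 34 genes), and at 100 mg/kg Cngb3, a cyclic nucleotide channel subunit, rose from 3.07 to 5.91 CPM (0.95 ± 0.16, 0.0202, DESeq2 40). Both calls were lost in alternatives, and the count at 100 mg/kg was 0 without vehicle M1, M2, F2 or F3 or 100 mg/kg M4, F1 or F2, and 2 without vehicle F4. Between doses 0 passed (2040 at an unadjusted p under 0.05, DESeq2 1). Of 14 leukocyte genes, 11 were higher in Q175 adjusted over the list alone, Cd79a by 1.89 and Cd3e by 2.03 (median 1.87, 4.87e-08, and adjusted p = 0.512 with an estimated correlation). They were lower at 30 mg/kg (9 of 14, −1.52, 1.04e-09, 0.31) and at 100 mg/kg (9 of 14, −1.32, 0.000827, 0.756). Cd79a, of B cells, was 45.3 CPM in vehicle F2, 12.1 in vehicle F3 and 0.738 to 4.86 in every other heart. PPAR targets were lower in Q175, 4 of 28 adjusted over the list alone (2.9e-05, and adjusted p = 0.456 with an estimated correlation). At 30 mg/kg, conduction and contraction genes (23, 1.14e-06) and MEF2 targets (25, 3.11e-05) were higher, at adjusted p = 0.31 with an estimated correlation, and ribosomal proteins lower (8.65e-09, and adjusted p = 0.645 with an estimated correlation). At 100 mg/kg all 74 oxidative phosphorylation genes lay above 0 (2.93e-21, and adjusted p = 0.756 with an estimated correlation).

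In liver, the single genotype call was Abhd1, 12.3-fold higher in Q175, at 22.1 ± 3.93 against 1.79 ± 0.476 CPM (3.62 ± 0.41, adjusted p = 1.18e-05, DESeq2 5 genes). The count was 3 without vehicle M3 and 2 without vehicle M4, 30 mg/kg M3, M4 or F3 or 100 mg/kg F2. Abhd1 overlaps Preb, which differed by 0.03 (0.934), and counting is not stated to use strand, so its reads are uncertain. All 25 cholesterol synthesis genes lay higher (median 0.40, 5.02e-12, and adjusted p = 0.84 with an estimated correlation).

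**Figure D4:**
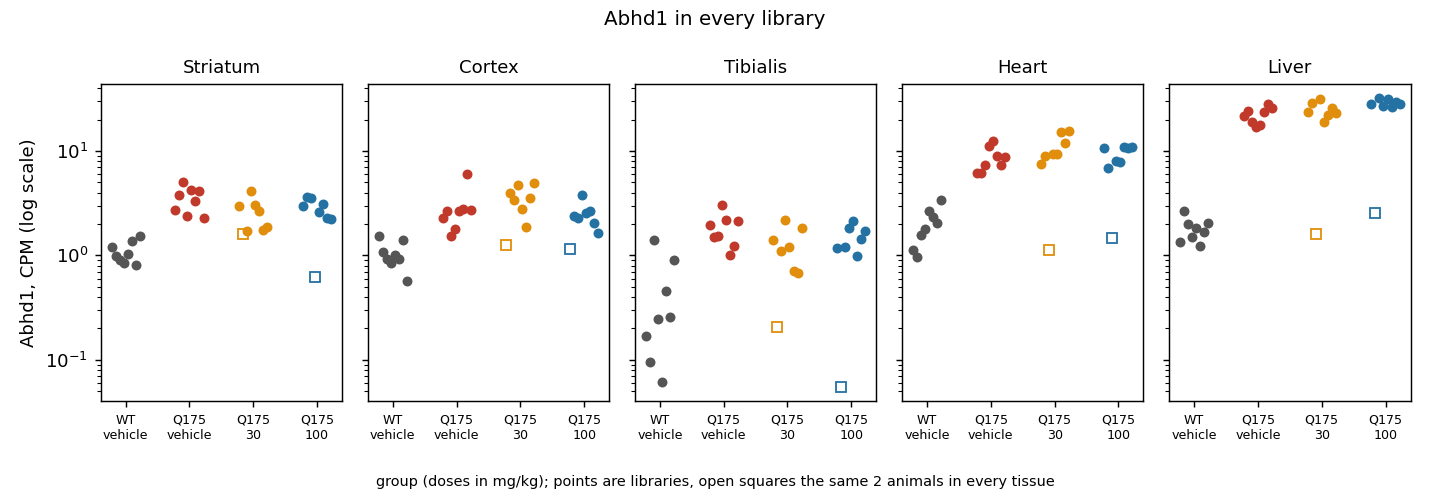
Abhd1 in CPM (vertical axis, log scale) per library by tissue and group, with open squares for the same 2 animals, at or below the highest WT library except for 1 in striatum (1.60 against a highest WT of 1.52). Liver libraries of the other Q175 mice sit between 16.9 and 32 CPM, above the highest WT at 2.72.

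At 30 mg/kg, liver showed a shift of fatty acid oxidation genes as a group and no single call. With edgeR 0 genes passed (573 at an unadjusted p under 0.05, DESeq2 5), and 3 did without vehicle M1. Of 32 targets of PPAR alpha, the fatty acid sensor of liver, 15 rose adjusted over the list alone (median 0.29, 1.61e-23, and adjusted p = 0.0439 with an estimated correlation). Ehhadh, of peroxisomal oxidation, differed by 0.71 and Abcc4, an export pump, by 0.82 ± 0.20, each at 0.509 over all genes. Xenobiotic metabolism genes were higher (43, median 0.17, 6.89e-06, and adjusted p = 0.457 with an estimated correlation), and macrophage (3.72e-06, 0.756), unfolded protein response (0.000963, 0.383) and endothelial genes (0.00158, 0.894) lower, the value after each p being that with an estimated correlation. Lowest in p were Slc27a1, a fatty acid transporter (0.76, 0.283), Peg3, an imprinted factor (0.93), and Serpine2, a protease inhibitor (−0.86), the last pair at 0.337.

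At 100 mg/kg, genes of fatty acid oxidation and xenobiotic metabolism rose in liver. Abcc4 rose from 7.05 ± 4.07 to 31.7 ± 13.2 CPM and Me1, malic enzyme, from 145 ± 67.7 to 489 ± 73.5. Vnn1, a pantetheinase, rose from 35.2 ± 20.7 to 120.7 ± 43.9 CPM, and Ehhadh from 479.8 to 1307. Hpx, the haem carrier, fell from 4336 ± 1604 to 2271 ± 185 CPM. Of 15001 genes tested, 617 rose and 411 fell (DESeq2, 788 and 576), 385 by over 1.5-fold and 180 by over 2-fold, and the count was 652 without vehicle F4. It was also lower without a sex term, and with limma on FPKM a larger share of the calls were higher.

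**Figure D5:**
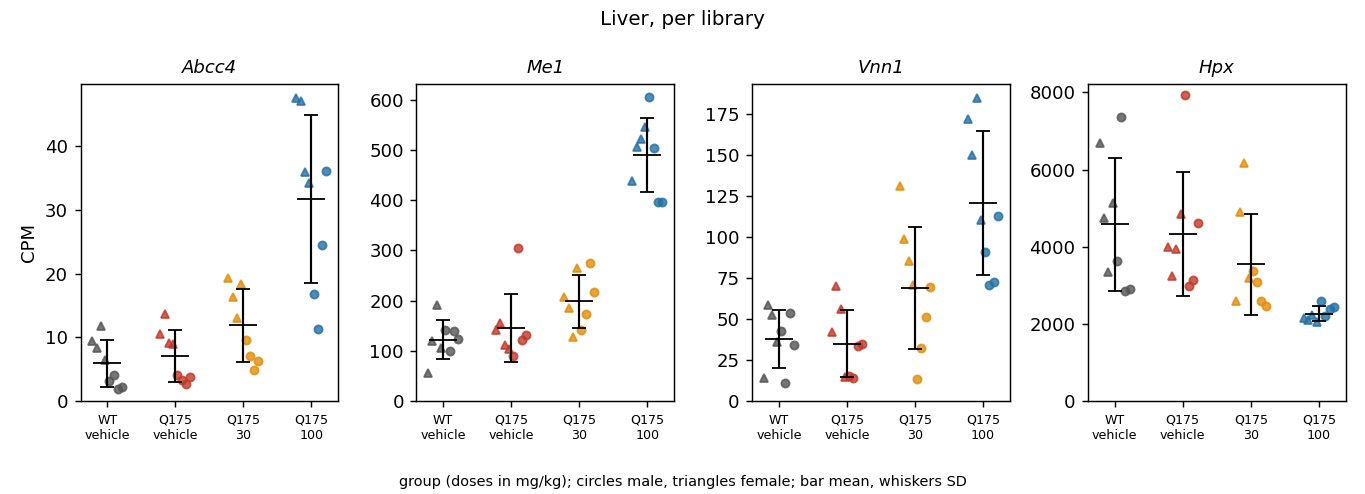
CPM of Abcc4, Me1, Vnn1 and Hpx (vertical axes) in each liver library by group, with circles for males, triangles for females and bars for mean ± SD. Me1 averaged 145 CPM on vehicle, 199 at 30 mg/kg and 489 at 100 mg/kg.

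Of the 32 PPAR alpha targets, 21 rose, 24 adjusted over the list alone, and 0 fell (median 0.56, camera adjusted p = 7.26e-22, and 0.0304 with an estimated correlation). Abcc4 changed by 2.31 ± 0.21 (adjusted p = 5.09e-08), Me1 by 1.76 ± 0.22 (8.86e-06), Ehhadh by 1.42 ± 0.18 (8.86e-06) and Vnn1 by 1.79 ± 0.35 (0.0018). Acot2, a mitochondrial thioesterase (1.22, 1.82e-06), Pex11a, of peroxisome division (1.01, 1.28e-05), Slc25a20, the carnitine carrier (0.66), Cd36, fatty acid uptake (0.95), and Cyp4a14 (1.66, 0.000697) followed, the last with paralogs that make it uncertain, as for Cyp4a10, Acot1 and Acaa1b. Of 43 xenobiotic genes, 18 rose, 25 adjusted over the list alone (median 0.45, 5.09e-17, and 0.0304 estimated). Cyp2b10, the classic target of CAR, rose by 2.43 ± 0.36 (0.000135, from 103 to 481 CPM), Cyp2c29 by 1.49 ± 0.19 (1.14e-05), Gstm1 by 1.15, Nqo1, a quinone reductase, by 0.69 and Ephx1, an epoxide hydrolase, by 0.69, the first 3 being in families with shared reads. The fitted log2 values were highest for Cyp2b13 (3.31), Sult2a3 (3.11), Mogat1, of triglyceride synthesis (2.87 ± 0.49), Mup-ps14 (2.74) and Slc39a5, a zinc transporter (2.72 ± 0.38, 3.66e-05). Cyp2b13 was 0.349 CPM in males on vehicle and 13.7 ± 21.98 at 100 mg/kg, and 326 and 455 in females, so its value rests on males near 0.

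Of 20 fatty acid synthesis genes, 4 rose, 10 adjusted over the list alone (0.48, 2.42e-08, and adjusted p = 0.358 with an estimated correlation), Pnpla3 by 1.39, Elovl6 by 0.78 and Thrsp by 1.39. Of 21 acute phase genes, 6 fell, 13 adjusted over the list alone (−0.59, 5.08e-08, and adjusted p = 0.47 with an estimated correlation): Hpx by −0.93 ± 0.21, the fibrinogen chains Fga, Fgb and Fgg by −0.69, −0.60 and −0.59, and Itih4 by −0.63. Cholesterol synthesis (25, 0.40, 2.89e-06, and adjusted p = 0.741 with an estimated correlation) had 2 calls in both counts, Pmvk (0.65) and Acat2 (0.59). The mitochondrial genome had 4 of 13 in both counts (0.00404, and adjusted p = 0.741 with an estimated correlation), among them mt-Nd1 (0.46) and mt-Nd6 (0.52). Oxidative phosphorylation (2.42e-08) had 1, Ndufa10 (0.24), and 0 adjusted over the list alone, and ribosomal proteins were higher (0.00246), both at adjusted p = 0.797 with an estimated correlation. The unfolded protein response fell in 3 of 24 in both counts, Chac1 by −1.21 and Herpud1 by −0.70 (0.0272, and adjusted p = 0.702 with an estimated correlation), and fibroblast genes in 1 of 16, Col5a1 by −0.41, with 3 adjusted over the list alone (0.0272, 0.797). Calls outside called lists were Hspe1 (0.46) and Hspb1 (0.80) of heat shock (3 of 16, 6 adjusted over the list alone, 0.13), Usp18 (0.69) and Ifit3 (0.50) of interferon (2 of 24, 3 higher and 1 lower, 0.107), Abcc3 (0.39) of bile acid transport (1 of 15, 0.258), Hdac2 (0.20) of deacetylases (1 of 14, 3 higher and 1 lower, 0.297), Per1 (−0.82) of the clock (1 of 21, 0.623), and Btg2 (−1.36) and Eda2r (−1.49) of p53 (2 of 17, 0.623). The largest falls were Tff3 (−5.12), Ntrk2 (−3.56), Cib3 (−3.38), Clec2h (−3.19) and Lrtm2 (−3.04). These 5, Cyp2b13, Sult2a3, Cd36, Thrsp, Hspb1, Usp18, Ifit3, Pmvk, Acat2, Ndufa10, Col5a1, Herpud1, Chac1, Per1, Btg2 and Eda2r lost their call in at least 1 alternative, Btg2 without vehicle M1 and Cyp2b13 without 100 mg/kg M4.

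Sex-biased liver genes, which follow growth hormone, were also compared between males and females. Of 19 female-biased genes 4 rose and 5 adjusted over the list alone (0.13), and of 15 male-biased genes 2 fell and adjusted over the list alone 1 rose and 3 fell (0.253). The median change of female-biased genes was 0.61 in males and 0.10 in females (limma's camera on the interaction, p = 6.07e-07, and p = 0.0185 with an estimated correlation). For male-biased genes it was −0.75 and −0.01 (camera in limma, p = 0.000347, and p = 0.112 with an estimated correlation). Male-biased genes near 0 in females leave little room for a fall there, which limits this comparison. In the 4 males of each group, Cyp2b9 went from 8.61 to 176 ± 134 CPM and Serpina1e, an antitrypsin with close paralogs, from 4182 ± 1833 to 734 ± 399. In females, Cyp2b9 was 432 and 471 CPM and Serpina1e 81.2 and 13.7. C6, of complement, was 301 and 139.7 CPM in males and 24.4 and 12.5 in females. Sult2a3 was 10.03 and 89.1 CPM in females and 0.0135 and 0.0536 in males. Hsd3b5 was 80.1 and 22.8 CPM in males and 0.166 and 0.126 in females, while in males Cyp4a12a was 176 and 325 and Elovl3 381 and 362. Serpina1e lost its call without the sex term, and Cyp2b9 and C6 lost theirs when single libraries were left out.

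Between the doses, liver had 45 genes higher and 49 lower at 100 than at 30 mg/kg (DESeq2 277). With limma on FPKM most calls were higher, and fewer genes passed without a sex term or without libraries over the limit for another tissue. Abcc4 differed by 1.49 ± 0.20 (adjusted p = 0.000384; the call was lost without the sex term) and Me1 by 1.30 ± 0.21 (0.00225), while Vnn1 (0.85) did not pass (0.268). The count of 94 was 47 without 100 mg/kg M4 or F1, 40, 58, 48 and 236 without 30 mg/kg M2, M3, F3 and F4, and 184 without WT F2. Against WT, 100 mg/kg gave 644 higher and 438 lower liver genes. For 30 mg/kg there were 8, chosen after their values were seen: Abhd1 (3.62), Abcc4 (1.08), Cyp4a32 (0.96), Acot2 (0.74), Casc4 (0.70), Galnt11 (0.68) and Pisd (0.26) higher and Irf5, of macrophage activation (−0.82), lower. That count was 4 without 30 mg/kg F1 or WT F4 and 5 without 30 mg/kg M2.

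In cortex, 6 genes were higher and 116 lower at 100 than at 30 mg/kg, with 0 called without 30 mg/kg M3 or F4, the libraries with tibialis transcripts. The count of 122 was 62, 64, 61, 57, 53, 52 and 52 without 100 mg/kg M1, M2, M3, M4, F1, F2 and F3, and 4226 without 100 mg/kg F4. It was 6459 and 7152 without 30 mg/kg M1 and M2, 6915 and 2576 without vehicle M3 and F4, and 2779 and 4283 without WT F2 and F3. Against WT, 82 were higher and 39 lower at 30 mg/kg, in all 121, with 2 without 30 mg/kg M3, 9 without its F4, 188 without its M2, and 62, 60 and 79 without WT F2, F4 and M4. Against WT, 8 passed at 100 mg/kg, chosen here after their values were seen: Slitrk6 (0.88), Enpp6, of oligodendrocytes (0.79), and 2600014E21Rik (0.52) higher, and Adam33 (−0.86), Mas1 (−0.46), Hipk4 (−0.43), Stard8 (−0.42) and Glul, glutamine synthetase (−0.29), lower. It was 5 without WT F1 or 100 mg/kg M3, F2 or F4, 4 without WT M2, M3 or F3 or 100 mg/kg M4 or F3, 30 without WT F2 and 23 without vehicle M3. In heart, Abhd1 was the gene higher than WT at 30 mg/kg (2.30 ± 0.32), and at 100 mg/kg Abhd1 (2.13 ± 0.32) and Serpine2 (0.41) were higher and Scn4b (−0.88) lower. The last count of 3 was 1 without WT M1, M4, F3 or F4, vehicle F1 or F4, 30 mg/kg M3, F3 or F4 or 100 mg/kg M1, M2, M3, M4, F1 or F3.

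Genotype effects in striatum were tested against those in the other tissues of the same animals with limma. They differed for 25 genes against cortex (11 higher, 14 lower), 8 against tibialis (2, 6), 118 against heart (43, 75) and 74 against liver (24, 50). Against cortex, Sfmbt2 rose more in striatum by 1.18 (adjusted p = 0.00112) and Wt1 by 3.37 (0.0055), and Vrk1, a chromatin kinase, changed by −0.67 (0.00105) and Krt9 by −0.78 relative to cortex. Ddit4l, an mTOR inhibitor, fell more in striatum than in tibialis (−1.69) and heart (−1.66), as did Phex relative to tibialis (−1.89). The count against tibialis was 0 without libraries holding transcripts of the other sex. Dsp rose more than in heart (1.82), and Wt1 more than in heart (4.11) and liver (4.59, 0.00196). These genes were chosen after their values were seen. At 100 mg/kg, 363 genes differed between striatum and liver (128 higher, 235 lower), Abcc4 by −2.22 (2.5e-07), Me1 by −1.73 and Ehhadh by −1.35. Against cortex, tibialis and heart 0 did (244, 220 and 3206 at an unadjusted p under 0.05, limma, and DESeq2 was not run on these differences).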

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

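All tests of the explanations weighed in this part were chosen only after the results they concern were seen, while the interactions with sex, the tissue differences and the splits of the libraries were fixed before. Values apart from their group were looked for in 180 groups of 8 libraries, where a sample stood out if its gap to the nearest other was large against the range of the group. It marked 12, and chance marks about 1 in 20 groups.

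Genes of other tissues were called in comparisons of brain. Cortex 30 mg/kg F4 and M3 held 27.2% and 6.34% of tibialis transcripts, tibialis 100 mg/kg M1, WT F3 and WT M4 held 11.7%, 11.8% and 6.26% of cortex transcripts, and WT striata M1, M2 and M3 held 0.242%, 0.131% and 0.0669% of liver transcripts. A response of cortex to 30 mg/kg is argued against, because only 2 of its 8 libraries lay above every vehicle library in the called genes. Muscle RNA from other animals remains, with 2 of 8 libraries over 1%, and both also held transcripts of the other sex. Liver RNA in WT striata may account for part of the falls, since 9 of the 26 liver genes still lay above every Q175 vehicle library in the WT libraries under the limit and the other 17 did not, and whether it entered at dissection or later is not given.

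Abhd1 was higher in Q175 mice in striatum, heart and liver, on chromosome 5 at 30950066 to 30955091 with Htt at 34761740 to 34912534 (GENCODE M21, GRCm38, as the authors' build is not given in the sources used here). A direct product of the knock-in allele is argued against by 2 Q175 animals with Abhd1 at the WT level in liver and heart and striatal Sfmbt2 above every WT animal, and so are WT animals under a Q175 label, with 0 such animals also at the WT level of Sfmbt2. A strain variant linked to Htt stays open, since a crossover between Htt and Abhd1 could have left the pair of animals with the other variant. With Abhd1 and Htt left out, 15 of 168 tested genes within 10 Mb of Htt were called for genotype in striatum and 975 of 17059 elsewhere (odds ratio 1.62, Fisher's exact test, two-sided, p = 0.0922), too few to decide. In striatum these animals, 30 mg/kg F2 and 100 mg/kg F4, had 1.60 and 0.614 CPM, beside a highest WT of 1.52, and counting over Preb without a stated strand stays open too.

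Wt1 lay at the WT level in 3 Q175 striata. A WT sample under a Q175 label is argued against, because the lowest of them stood at 0.368 on the axis from WT to Q175 and the highest WT animal at 0.123, and their Sfmbt2 was 5.43, 5.62 and 6.38 CPM, above the highest WT at 4.72. WT RNA mixed into a Q175 library is argued against in all 3, since Wt1 was lower than the share left on the axis would give, and the compound because 1 of the animals was given vehicle. A shorter CAG repeat in these animals might give a weaker response, but no repeat lengths are given, so this was not tested.

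Single libraries stood apart from the rest of their group in the following values, in CPM. In striatum, Sfmbt2 was 5.43 in vehicle M2 (others 10.3 to 14.1) and Hdac4 was 26.0 in 30 mg/kg F2 (16.5 to 19.95). In cortex, Hdac4 was 57.6 in WT F3 (31.6 to 40.1), and the total of 100 mg/kg M3 was 30.3 M counts (34.4 to 36). Htt was 15.7 in tibialis 100 mg/kg M1 (5.84 to 9.42) and 9.54 in liver WT F2 (24.1 to 29.5). Abhd1 was 1.47 in heart 100 mg/kg F3 (6.84 to 11.1), 1.61 in liver 30 mg/kg F3 (18.8 to 31.5) and 2.54 in liver 100 mg/kg F2 (26.2 to 32). In liver, Me1 was 304 in vehicle M2 (89.1 to 155), Hdac4 was 11.2 in 30 mg/kg F3 (6.40 to 8.51) and Hdac7 was 12.7 in 100 mg/kg F2 (5.85 to 8.40).

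Effects differed between groups of samples in 6 tests. Gc, a liver plasma protein, was the 1 gene whose genotype effect in striatum differed by sex (722 at an unadjusted p under 0.05, DESeq2 12), and chance could not be excluded, as 4 of 21 splits called as many, up to 12 genes. The 3 WT striata with liver transcripts, M1, M2 and M3, were all males, and the genotype effect on Gc was 1.2 without libraries over the tissue limit, so liver RNA in WT males stays open as a source. The genotype effect in striatum differed from that in cortex for 25 genes (chance excluded, 1 of 100 splits, highest other 3) and from that in heart for 118 (1 of 100, highest other 1). For tibialis there were 8 and for liver 74, with 2 of 100 splits calling as many for each. By that share alone chance was excluded. The count against tibialis was 0 without libraries holding transcripts of the other sex, however, and 8 genes are a small count. The highest other splits called 5862 and 980 genes, more than the real counts, so the share is weak evidence against chance for both. A structure of the samples may lie behind such splits and was not tested. At 100 mg/kg, 363 genes differed between striatum and liver (1 of 100 splits, highest other 7). Cortex, tibialis and heart gave 0 with limma (244, 220 and 3206 at an unadjusted p under 0.05), where all 100 splits gave as many and other splits reached 5480, 3707 and 3665.

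Interactions with sex elsewhere gave 0 genes with edgeR, so that all 21 splits gave as many. In the order of count at an unadjusted p under 0.05, DESeq2 count and highest other split, they were 625, 0 and 0 for 100 mg/kg in striatum, 1808, 2 and 0 for genotype and 739, 3 and 0 for 100 mg/kg in cortex, and 253, 3 and 0 and 863, 1 and 0 in tibialis. In heart they were 1925, 114 and 0 and 3467, 317 and 2580, and in liver 1106, 1 and 0 and 611, 6 and 216. The splits of heart and liver that called 2580 and 216 genes may reflect a structure of the samples, which was not tested.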

How the results depend on the processing

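The tissue limit, the other-sex, the column name and the own-part alternatives were chosen only after the data were seen, and the rest before. Counts are of genes past the threshold, each beside its value in the report, and unless a reason is given the cause was not tested. Setting aside the fits that left out single libraries, 316 counts and correlations stayed within 1.5 times or, for correlations, within the range over splits. Of the rest, 70 grew, 53 shrank and 9 moved out of that range. Direction was not part of this rule. Of values of named genes, 2156 kept their side, 228 lost the call, 24 gained it and 12 reversed, and of lists 1176 kept it, 248 lost it, 13 gained it and 3 reversed.

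At a threshold of 0.1, which admits more genes by construction, genotype gave 1577 genes in striatum (992), 25 in cortex (6), 2 in heart (1) and 2 in liver (1). Cortex gave 90 at 30 mg/kg (56), 7631 between doses (122), 205 for 30 mg/kg against WT (121) and 30 for 100 mg/kg against WT (8). Liver gave 1656 at 100 mg/kg (1028), 233 between doses (94), 21 for 30 mg/kg against WT (8) and 1630 for 100 mg/kg against WT (1082).

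With DESeq2, striatum gave 3 genes at 100 mg/kg (0) and 12 for genotype by sex (1). Cortex gave 34 for genotype (6), 3 at 30 mg/kg (56), 1 at 100 mg/kg (0), 4948 between doses (122), 63 for 100 mg/kg against WT (8), and 2 and 3 for genotype and 100 mg/kg by sex (0). Tibialis, at 0 with edgeR throughout, gave 4 for genotype, 10 at 30 mg/kg, 1 at 100 mg/kg, 10 between doses, 11 and 2 for the doses against WT, and 3 and 1 by sex. Heart gave 95 for genotype (1), 34 at 30 mg/kg (1), 40 at 100 mg/kg (1), 1 between doses (0), 2 and 25 for the doses against WT (1 and 3), and 114 and 317 by sex (0). Liver gave 5 for genotype (1), 5 at 30 mg/kg (0), 277 between doses (94), 47 for 30 mg/kg against WT (8), and 1 and 6 by sex (0). The cause was not tested.

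With 2 surrogate variables, striatum gave 3596 genes for genotype and 4559 and 3727 for the doses against WT (1152 and 851). Cortex gave 332 for genotype, 0 at 30 mg/kg, 0 between doses, and 460 and 345 against WT. Tibialis gave 1 for genotype and 14 for 100 mg/kg against WT, heart 3 for genotype and 2 at 100 mg/kg, and liver 179 between doses and 24 for 30 mg/kg against WT. Surrogate variables are estimated from the same libraries, and the cause was not tested.

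With only the groups compared, a fit on fewer samples, cortex gave 0 genes for genotype, 0 at 30 mg/kg, 8246 between doses and 2 for each dose against WT. Heart gave 3 for genotype, 0 at 30 mg/kg, 0 at 100 mg/kg and 0 for 30 mg/kg against WT, and liver 2 for genotype and 3 for 30 mg/kg against WT. Without a sex term the counts were 195 in cortex between doses and 5 for 100 mg/kg against WT, 2 for heart genotype and 1 for heart 100 mg/kg against WT. In liver they were 542 at 100 mg/kg, 36 between doses, and 4 and 635 for the doses against WT. With no filter they were 0 for striatum genotype by sex, 0 for cortex genotype, 4 for cortex 100 mg/kg against WT, 1 for heart 100 mg/kg against WT and 61 for liver between doses, more genes being tested there.

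With limma on FPKM, cortex gave 3 genes for genotype, 0 at 30 mg/kg, 0 between doses and 16 for 30 mg/kg against WT, heart 0 at 100 mg/kg, and liver 191 between doses and 4 for 30 mg/kg against WT. Of the calls, 582 were higher and 401 lower for striatum genotype (447 and 545 with edgeR), 766 and 261 for liver at 100 mg/kg (617 and 411), and 155 and 36 for liver between doses (45 and 49). With the replicate number as a block, cortex gave 0 genes for genotype, 0 at 30 mg/kg, 0 between doses and 4 for 30 mg/kg against WT, and heart 0 at 100 mg/kg. Deviations of the 48 pairs with the same number correlated at a mean of 0.0165 in striatum, −0.0270 in cortex, 0.0629 in tibialis, 0.0432 in heart and 0.0170 in liver. Of 32 libraries, 10, 7, 15, 10 and 9 lay closest to their own number, out of 4 numbers possible for each. In striatum, cortex, heart and liver there was thus little sign that the number marks a pair. In tibialis, with 15 and a mean of −0.0196 for pairs with other numbers, a link between libraries of the same number stays open.

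Without outlying libraries, cortex gave 11 genes for genotype, 6915 between doses and 23 for 100 mg/kg against WT, tibialis 349 for genotype and 283 and 341 for the doses against WT, and heart 1 for 100 mg/kg against WT. The tibialis fits still held WT F3 and M4 with their cortex transcripts. Without libraries holding transcripts of the other sex, cortex gave 11 for genotype, 0 at 30 mg/kg, 0 between doses and 0 for 30 mg/kg against WT, and the difference of striatum and tibialis 0 for genotype (8). Without libraries over the limit for another tissue, striatum gave 418 for genotype and 546 and 353 for the doses against WT, cortex 0 at 30 mg/kg, 0 between doses and 0 for 30 mg/kg against WT, heart 0 at 100 mg/kg and 1 for 100 mg/kg against WT, and liver 54 between doses and 2 for 30 mg/kg against WT. With the column name style as a covariate, cortex gave 0 at 30 mg/kg, 76 between doses and 10 and 4 for the doses against WT, heart 1 for 100 mg/kg against WT and liver 2 for genotype. These fits rest on fewer samples or another covariate, and the cause was not tested further. Counting genes kept in either tissue, the genotype difference was 21 for tibialis (8) and 167 for liver (74), more genes being tested.

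Signs reversed without libraries over the tissue limit for Apoa2 (0.50), Gc (1.2) and Alb (0.50) in striatum for genotype, and in cortex at 30 mg/kg for Myh4 (−2.49), Tnni2 (−2.69), Mb (−0.51) and Mylpf (−1.03). Without libraries holding transcripts of the other sex they reversed in cortex for Myh4 (−2.54), Tnnc2 (−2.91), Tnni2 (−2.91), Mb (−0.63) and Mylpf (−1.10). There the list of nuclear oxidative phosphorylation also turned (adjusted p = 0.343), as did in tibialis for genotype the homeobox and Polycomb targets (0.117) and the mitochondrial genome (0.0190). For the single genes, the libraries left out held transcripts of liver or muscle, and for the lists the cause was not tested.

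The correlation of genotype and dose effects in striatum was −0.364 at 30 mg/kg and −0.425 at 100 mg/kg over genes of at least 5 CPM, −0.331 and −0.402 on FPKM, and, for genotype genes chosen on the part that gives the genotype effect, 0.133 and −0.146. The correlation of the doses was 0.688 and 0.632 in the first pair of settings, and the tibialis value at 100 mg/kg was −0.0876 on FPKM. The cause was not tested.

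Leaving out each of 32 libraries in turn, the count for genotype ranged from 663 to 1349 in striatum, 0 to 13 in cortex, 0 to 349 in tibialis, 1 to 4 in heart and 1 to 3 in liver. At 30 mg/kg it stayed at 0 in striatum and tibialis and at 1 in heart, and ranged from 0 to 108 in cortex and 0 to 3 in liver. At 100 mg/kg it was 0 throughout in striatum, cortex and tibialis, 0 to 2 in heart and 652 to 1327 in liver. Between doses it was 0 in striatum, tibialis and heart, 0 to 7152 in cortex and 40 to 236 in liver. Against WT it was 868 to 1390 and 581 to 960 in striatum, 2 to 188 and 4 to 30 in cortex, 0 to 283 and 0 to 341 in tibialis, 1 and 1 to 4 in heart, and 4 to 12 and 789 to 1440 in liver. Calls of single genes were lost in 24 of these fits for liver Thrsp, 23 for Hspb1, 18 for Col5a1, 17 for Cxcl1, 15 for Cib3, 12 for C6, 11 for Ndufa10, 10 for Usp18 and Per1, 9 for Pmvk, 8 for Cyp2b9, 6 for Chac1 and Eda2r, 4 for Tff3 and Ifit3 and 1 for Btg2 and Cyp2b13. In striatum they were lost in 16 for Zbed6, 9 for Gemin4, 7 for Insig1 and Abca7, 5 for Tfap2b and Alb, 4 for Herpud1, 3 for Sirt5, 2 for Gc and 1 for Car3 and Apoa2 (without WT M1). At these depths and spreads, 1.5-fold changes were recovered in 24.2% of simulated cases in tibialis and 64% in heart.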

Other observations

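The tests of sex-biased liver genes were written before their own results were seen but after the 100 mg/kg comparison, and the splits were fixed before the data were examined.

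For part of the sex-biased liver genes, the change at 100 mg/kg may be a move of male livers toward the female pattern. As a list, male-biased genes fell more in males than in females (camera in limma, p = 0.000347, and p = 0.112 with an estimated correlation), and female-biased genes rose more (p = 6.07e-07, and p = 0.0185 with an estimated correlation). Some male-biased genes were near 0 in females on vehicle, such as Hsd3b5 (0.166 CPM) and Cyp4a12a (0.541). A fall in females could hardly show for these, which limits the comparison for male-biased genes. Cyp4a12a, a male-biased gene, went the other way in males, from 176 to 325 CPM, Elovl3 was 381 and 362, Serpina1e fell in females too (81.2 to 13.7 CPM, males 4182 to 734), as did C6 (24.4 to 12.5, males 301 to 139.7), and Sult2a3, a female-biased gene, rose in females (10.03 to 89.1) and was 0.0135 and 0.0536 in males, so the pattern is not shared by all these genes. Of single genes, 0 passed for the interaction with edgeR (611 at an unadjusted p under 0.05, DESeq2 6). Hormones were not measured, and induction of Cyp2b genes by the compound in males alone stays open.

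For each comparison, the libraries of the groups compared were split in 20 other ways into groups of the same size. Chance was excluded (1 of 21 splits) for genotype in striatum, with 992 genes and 5 in the highest other split, for striatum at 30 and 100 mg/kg against WT (1152 and 851, highest other 0 for both), and for liver at 100 mg/kg (1028, highest other 0). It was also excluded for liver at 100 mg/kg against WT (1082, highest other 1). Liver 30 mg/kg against WT (8 genes, highest other 1), cortex genotype (6, 0), cortex 100 mg/kg against WT (8, 0) and heart 100 mg/kg against WT (3, 0) also had 1 of 21. That is the lowest share 21 splits can give, so counts this small are weak evidence against chance. Leaving out single libraries took them to as few as 4, 0, 4 and 1. Cortex 100 against 30 mg/kg (122, highest other 89) had 1 of 21 too, but 0 genes without 30 mg/kg M3 or F4, which held tibialis transcripts. For heart at 30 mg/kg, 1 of 21 splits called as many (1 gene, highest other 0), but a count of 1 is weak evidence against chance, and it was 0 with only the 2 groups compared.

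Chance could not be excluded for cortex at 30 mg/kg (56 genes, 6 of 21 splits as many, highest other 70), cortex 30 mg/kg against WT (121, 3 of 21, 4123), heart 100 mg/kg (1, 2 of 21, 3) and liver 100 against 30 mg/kg (94, 2 of 21, 271). Abhd1 was the 1 gene called for heart genotype (2 of 21 splits called as many, highest other 1), heart 30 mg/kg against WT (4 of 21, 73) and liver genotype (2 of 21, 1). Any 1 gene in another split matches such a count, so it decides nothing about Abhd1, which was at most 2.72 CPM in WT livers and at least 16.9 in Q175 livers other than those of 2 animals, and in heart at most 3.37 and at least 6.14. The splits with 4123 and 73 genes may reflect a structure of the samples, which was not tested.

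Where the real count was 0 all 21 splits gave as many. The highest other split was 0 for the striatal doses and the striatal comparison of doses, for cortex at 100 mg/kg, for tibialis at 100 mg/kg and at 30 mg/kg against WT, and for heart 100 against 30 mg/kg. It was 1 for tibialis and liver at 30 mg/kg, 80 for tibialis 100 against 30 mg/kg, 1447 for tibialis genotype and 874 for tibialis 100 mg/kg against WT. The last pair and the 80 genes may reflect a structure of the samples, such as the cortex transcripts in tibialis 100 mg/kg M1, WT F3 and WT M4, which was not tested.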
